A study of Mus musculus with 16 samples.

How the data were processed

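RNA of sorted mouse HSCs was measured in 16 libraries, 4 each of vehicle, palbociclib, rapamycin and both drugs, prepared with a low-input kit from total RNA, per the labels' protocols. STAR 2.5.3a, RSEM 1.3.0 and SAMtools 1.3 and the mouse build mm10 are named, per the submitters' processing notes, without roles or settings. The annotation release and filters are not given in the sources used here. The authors deposited expected counts per gene, as RSEM estimates them, already in whole numbers, so rounding them again changed no value. The authors also deposited log2(TPM + 1) values of the same genes, with a pseudocount of 1. Undoing the log2 and subtracting 1 gave sums of 999999 to 1000001 per library. Both tables hold 50686 Ensembl gene IDs. In 1243 gene and library pairs the count was 0 with TPM above 0, and in 14 the count was above 0 with TPM at 0.

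Symbols and coordinates came from the GENCODE M21 annotation of GRCm38, the same build as mm10, which named 50376 of the IDs. The 310 without a symbol held at most 0.114% of a library and stayed in library sizes and tests. Estimated counts share reads between paralogs, so near-identical copies, such as the haemoglobin, immunoglobulin and Oas1 genes, are uncertain as single genes. Strand was not stated, so reads of overlapping and antisense genes may not be separated.

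Groups were taken from the sample titles. Total counts per library ran from 10133860 to 15328830. Replicates were compared before averaging. Within groups the 24 pairs of libraries correlated at 0.842 to 0.958 in log2 CPM. The lowest chi-square per degree of freedom of a pair was 24.5, so no library was a repeat of another of its group within sampling noise. Pairs between groups were not compared in this way. Intervals of single shares were not computed, since the spread between libraries was far above counting error.

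Genes were tested with edgeR 4.0.16 in R 4.3.3. filterByExpr with its minimum count of 10 and minimum total of 15 kept 15308 genes, which held 99.5% to 99.9% of the counts. TMM factors ran from 0.889 to 1.14. A model with a mean per group was fitted over all 16 libraries with 12 residual degrees of freedom, without covariates, and contrasts were tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment within each contrast at 0.05. The common dispersion was 0.311, a biological coefficient of variation of 55.8%. CPM values are TMM-scaled, and list means are means of log2 CPM with a prior count of 2. Fold changes are the fitted ones, with standard errors from the same fit.

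The design, the tests, 31 gene lists, the rule for named genes and the alternatives not named as added were set before the data were examined. The lists covered the cell cycle, both drug pathways, metabolism, ribosomes, stress, interferon, HSC identity and aging, and markers of other blood and stromal cells, and each had at least 5 tested members. Lists were tested with edgeR's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry (limma 3.58.1) stand beside it. Camera compares a list with the other genes, and fry asks whether a list's genes move in one direction. No list call in any comparison held with an estimated correlation. List means of 2 groups were compared with a two-sided exact permutation test, whose smallest p with 70 ways to choose 4 of 8 libraries is 0.029.

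The rule for named genes took, against vehicle, up to 8 genes per direction, and up to 4 for other contrasts. These had the largest log2 fold change among called genes with a mean log2 CPM of at least 1 and no overlap of the groups, leaving out predicted genes. Where fewer than 3 qualified, the 3 of smallest p were named as not qualifying. The rule also took 8 drug target genes, 4 sort markers and up to 4 members of smallest p of each called list. Oasl2, Mcm6 and the other members named with lists come from that last part.

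The correlation, the covariance and the share of genes with the same sign between the drugs were compared with 50 simulations of 3 unchanged groups, 1 of them in place of the shared vehicle, and with 6 ways to give each drug 2 vehicle libraries of its own. Shares of counts in neutrophil and in immunoglobulin and B cell genes were examined after the data were seen, as were 2 averaged contrasts, palbociclib over both rapamycin levels and the reverse.

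The analysis was tested on simulated negative binomial counts with the gene means, dispersions and library sizes of the real data and no difference between groups other than the one put in. Of 15308 genes, 50 were changed at each fold, drawn from genes outside the S-phase list with a mean of at least 2 CPM. Recovery among genes of lower expression was not tested. At 1.5-, 2-, 4- and 8-fold, edgeR recovered 0%, 18%, 68% and 80% for palbociclib against vehicle and the same shares for rapamycin against vehicle. It recovered 2%, 8%, 58% and 82% for the combination against vehicle, and 0%, 18%, 60% and 84% for the combination against palbociclib. For the combination against rapamycin it recovered 2%, 14%, 68% and 72%, and for rapamycin against palbociclib 2%, 22%, 56% and 74%. Between 1 and 4 of 15075 unchanged genes were called by edgeR. For palbociclib against vehicle, where the other tools were tested too, DESeq2 called 32 unchanged genes, limma-voom 2 and edgeR 1. An S-phase list shifted by 0.5 on the log2 scale was called by camera with the preset and with the estimated correlation in all 6 comparisons, and at most 1 of 30 unshifted lists was called. The simulated genes were independent, and with the real correlation between genes, regrouped libraries called a median of 9 to 11 of the 31 lists at the preset correlation. Changes of 2-fold or less were thus mostly below what 4 libraries per group and this spread could call gene by gene.

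Alternatives were RLE size factors, library totals alone, no filter, a filter at CPM 5 in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, limma on log2 TPM, the replicate number as a block, 1 surrogate variable (sva 3.50.0), only the 8 libraries compared, other gene sets in the library totals, each library left out in turn, an adjusted p of 0.1, and the other list tests. After the data were seen, 5 more were added: leaving out the 3 libraries whose median correlation with the others was under 0.88, 2 blood cell shares as covariates, robust shrinkage, the tests without blood lineage marker genes, and a replicate block of its own for the groups without and with palbociclib. Tables and figures used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.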

Results

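RNA was sequenced from haematopoietic stem cells (HSCs), the marrow cells that renew the blood for life, of C57BL/6J mice given 1 of 4 long-term treatments. Vehicle (20% DMSO and 40% PEG 400 in saline), palbociclib at 30.4 mg/kg, rapamycin at 6.4 mg/kg or both drugs were injected every 48 h for 85 days. Palbociclib inhibits the cyclin D kinases CDK4 and CDK6, which drive entry into the cell cycle, and rapamycin inhibits mTOR, the kinase that couples growth to nutrients. Each library came from 10000 cells in G0 or G1, sorted after depletion of lineage-positive cells with antibodies to CD150, CD48, Sca-1 and CD117. There were 4 libraries per group and 16 in all, with 10133860 to 15328830 counts per library and 16570 to 20418 genes detected. According to its title, the series asks whether cell size determines the potential of stem cells during aging, and the drugs here act on the cell cycle and on growth. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries, which may be partly technical.

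The libraries held differing amounts of RNA typical of blood cells other than HSCs, which the lineage depletion and the sort gate would be expected to remove. A list of 19 neutrophil granule genes made up 1.12% to 10.9% of the counts of single libraries. It shares Mpo and Ctsg with the list of multipotent progenitor markers, so it does not mark mature cells alone. Its mean share was 4.15% ± 2.69 (SD, n = 4) in vehicle, 7.12% ± 4.05 in palbociclib, 5.10% ± 2.78 in rapamycin and 4.49% ± 2.94 in combination libraries. Immunoglobulin and B cell genes made up 8.001% of vehicle replicate 4 and 0.00825% of combination replicate 2. Their mean share was 2.69% ± 3.58 in vehicle, 1.07% ± 0.730 in palbociclib, 0.0996% ± 0.0933 in rapamycin and 0.597% ± 0.485 in combination libraries (SD, n = 4). The rapamycin and vehicle libraries did not overlap in this last share, at the smallest p that 4 against 4 libraries allow (two-sided exact permutation p = 0.029, adjusted p = 0.172 over 6 tests added after the data were seen). In 18 planned exact permutation tests against vehicle, total counts, genes detected and the shares of the top 50 genes and of mitochondrially encoded, ribosomal protein and haemoglobin genes gave adjusted p between 0.77 and 0.83. In 3 libraries, vehicle 3, rapamycin 3 and vehicle 4, the median correlation with the other libraries was lowest, at 0.866, 0.871 and 0.88.

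**Figure D1:**
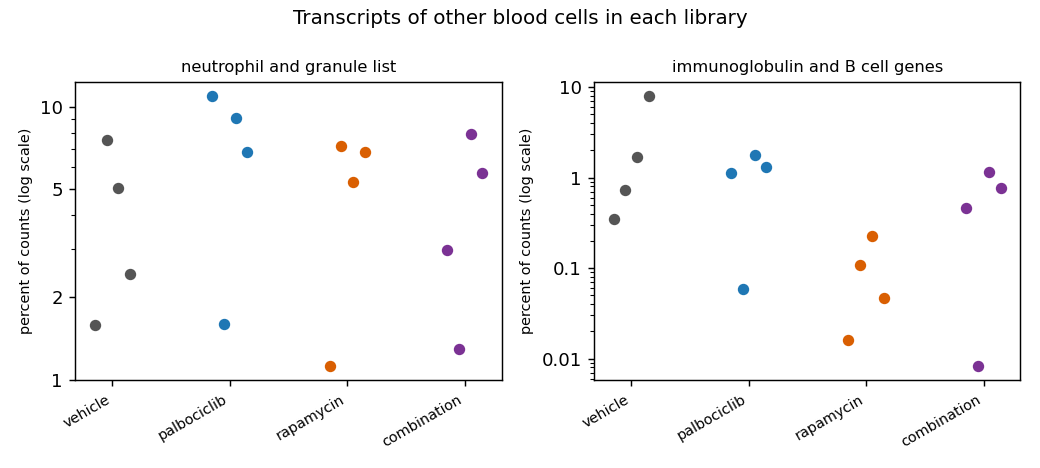
Share of each library's counts in neutrophil granule genes (left) and in immunoglobulin and B cell genes (right), in percent on log axes, with one point per library and 4 libraries per group. Neutrophil shares run from 1.12% to 10.9% with overlap between all groups, and the B cell shares of the rapamycin libraries lie below those of the vehicle libraries.

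The first comparison asked how palbociclib alone changed the stem cells. S-phase genes, targets of the E2F factors that CDK4/6 activity releases, had higher levels in palbociclib than in vehicle libraries. Of 33 members, 32 had positive fold changes, with a mean log2 fold change of 0.49. The list's mean log2 CPM was 6.74 ± 0.15 in palbociclib and 6.20 ± 0.22 in vehicle libraries (SD, n = 4), and all 4 palbociclib libraries lay above all 4 vehicle libraries. Pcna, the clamp of the replicative polymerase (ENSMUSG00000027342, chromosome 2, 132249162 to 132253314), averaged 452 ± 59.3 CPM against 282 ± 28.6. Mcm6, a subunit of the replicative helicase, averaged 597 ± 88.9 against 370 ± 51.9.

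No single S-phase gene passed the test over all genes, while 14 were called higher when adjusted over the list alone. The list test of edgeR gave an adjusted p of 6.13e-15 with a preset correlation between genes. With an estimated correlation its adjusted p = 0.0732, the lowest of the 31 lists in this comparison. The exact permutation test of the list means gave p = 0.029 and an adjusted p of 0.222. G2/M genes of mitosis had positive fold changes in 28 of 29 members, with 0 past the test over all genes, 4 adjusted over the list alone and a mean log2 fold change of 0.74 (edgeR adjusted p = 4.57e-12, and adjusted p = 0.449 with an estimated correlation). Bub1b, a kinase of the spindle checkpoint, averaged 123 ± 13.5 CPM against 60.5 ± 24.7 (n = 4). Across all 16 libraries the G2/M list mean followed the log2 share of neutrophil genes, with Pearson r = 0.725 (permutation p = 0.0014, adjusted p = 0.0056 over 4 relations chosen after the data were seen), Spearman rho = 0.729 (permutation p = 0.00223), and r = 0.661 without the 2 libraries farthest from the median share.

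Immediate early genes, which respond within minutes to growth factors and to handling, were lower after palbociclib in 21 of 23 members, with a mean log2 fold change of -0.52. None passed over all genes and 3 did adjusted over the list alone (edgeR adjusted p = 6.12e-08, and adjusted p = 0.123 with an estimated correlation). Jund averaged 279 ± 8.10 CPM after palbociclib and 498 ± 87.2 in vehicle, and Ier2 168 ± 27.6 and 265 ± 39.7 (SD, n = 4). Proteasome genes were higher in 26 of 31 members, with 4 called over the list alone and 0 over all genes (adjusted p = 0.00021, and adjusted p = 0.542 with an estimated correlation). Cytosolic ribosomal protein genes had negative fold changes in 69 of 78 members, 0 called either way (adjusted p = 8.9e-07, and adjusted p = 0.657 with an estimated correlation). Ribosome biogenesis genes were higher in 22 of 29, again with 0 called (adjusted p = 0.00139, and adjusted p = 0.449 with an estimated correlation). HSC identity genes were lower in 24 of 30 members, 0 of them called (adjusted p = 0.00377, and adjusted p = 0.657 with an estimated correlation). Genes known to be raised in aged HSCs were lower in 21 of 26, 0 of them called (adjusted p = 0.00706, and adjusted p = 0.655 with an estimated correlation). Mitochondrially encoded genes were higher in 13 of 13 members, 1 called over the list alone and 0 over all genes (adjusted p = 0.00296, and adjusted p = 0.655 with an estimated correlation). Their mean log2 CPM was 7.27 ± 0.13 in palbociclib and 6.51 ± 0.62 in vehicle libraries (SD, n = 4), without overlap (exact permutation p = 0.029, adjusted p = 0.222). Interferon response genes were higher in 30 of 33, with 0 called over all genes (adjusted p = 0.000254, and adjusted p = 0.655 with an estimated correlation). In the same libraries, markers of neutrophils were higher in 16 of 19 genes, those of stromal and endothelial cells in 10 of 11, and those of B cells lower in 10 of 11 (adjusted p = 0.00908, 0.00296 and 0.0135, with adjusted p = 0.683, 0.542 and 0.657 under an estimated correlation).

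No gene passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, in which 1456 of 15308 genes had an unadjusted p under 0.05 and 765 were expected by chance. DESeq2 called 137 genes, limma-voom 0 and limma on log2 TPM 0. The genes with the smallest p, which did not qualify, included Jpt2 (log2 fold change 0.69 ± 0.14 SE, edgeR adjusted p = 0.210), Prim2, a subunit of DNA primase (0.93 ± 0.19, adjusted p = 0.210), Pmepa1 (-2.62 ± 0.47, adjusted p = 0.207), Pnrc1 (-0.77 ± 0.14, adjusted p = 0.207) and Znrf2 (-1.54 ± 0.28, adjusted p = 0.207). Of the 31 lists, 14 were called with the preset correlation (8 higher and 6 lower), 0 with an estimated one and 2 by fry. Without vehicle replicate 4, 9 lists were called, and the mean log2 fold changes of B cell and T and NK cell markers turned from -1.97 and -1.27 to 0.52 and 0.17, so this single library set their direction. Without vehicle replicate 1, genes raised in aged HSCs went from -0.47 to -0.02 and HSC identity genes from -0.325 to -0.10, and neither list was called. Calls also ended for genes raised in aged HSCs without palbociclib 3, HSC identity genes without palbociclib 1 or 3, B cell markers without palbociclib 2 or 4, ribosomal protein and stromal genes without vehicle 4, neutrophil genes without vehicle 1 or 4 or palbociclib 1 or 3, mitochondrially encoded genes without vehicle 3, and interferon genes without palbociclib 3. S-phase, G2/M, immediate early, proteasome and ribosome biogenesis genes stayed called without any single library. Without the 3 libraries of lowest correlation, 1 gene was called, and the B cell and T cell lists turned to 1.21 and 1.16.

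The second comparison asked how rapamycin alone changed the cells. Bhlhe40, a transcription factor gene induced by stress and activation (ENSMUSG00000030103, chromosome 6, 108660629 to 108666925), fell to 16.5 ± 4.78 CPM from 66.8 ± 19.7 in vehicle (SD, n = 4), 4.04-fold lower. Its log2 fold change was -2.01 ± 0.25 (SE) with an edgeR adjusted p of 0.00721, and it was the 1 gene called of 15308. Socs3, a feedback inhibitor of cytokine signalling, averaged 16.9 ± 1.99 CPM against 41.1 ± 9.66 but did not pass (log2 fold change -1.28 ± 0.24, edgeR adjusted p = 0.217), nor did Selp, the adhesion molecule P-selectin, at 62.0 ± 17.5 against 153 ± 49.2 (-1.30 ± 0.25, adjusted p = 0.222). Car3, a carbonic anhydrase, averaged 8.36 ± 1.46 against 1.32 ± 0.293 (2.66 ± 0.43, adjusted p = 0.103).

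Genes of the amino acid and ATF4 response, which mTOR activity sustains, were lower after rapamycin in 16 of 19 members, 0 called over all genes and 1, Nupr1, adjusted over the list alone (edgeR adjusted p = 0.00105, and adjusted p = 0.296 with an estimated correlation). Glycolysis genes were lower in 16 of 19, with 0 called either way (adjusted p = 0.0179, and adjusted p = 0.551 with an estimated correlation), and Hk2, a hexokinase, averaged 44.8 ± 3.37 CPM against 77.5 ± 23.3. Nuclear-encoded oxidative phosphorylation genes were lower in 37 of 46 (adjusted p = 0.00105, and adjusted p = 0.583 with an estimated correlation), while mitochondrially encoded genes were higher in 12 of 13, with 8 called over the list alone and 0 over all genes (adjusted p = 7.71e-09, and adjusted p = 0.390 with an estimated correlation), although libraries of the groups overlapped in the list mean (exact permutation p = 0.143, adjusted p = 0.757). Genes raised in aged HSCs were lower in 21 of 26, with Selp and Nupr1 called over the list alone (adjusted p = 0.00226, and adjusted p = 0.551 with an estimated correlation). The S-phase list, with 17 of 33 members higher, was not called (adjusted p = 0.618), nor were the mTOR pathway components, with 11 of 20 higher (adjusted p = 0.524).

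Markers of stromal and endothelial cells, which the sort excludes, were higher in 11 of 11 genes, with a mean log2 fold change of 2.32, 4 called over the list alone and 0 over all genes (adjusted p = 7.71e-09, and adjusted p = 0.209 with an estimated correlation). Their levels were low, with Lepr, a marker of marrow stroma, at 28.7 CPM in rapamycin replicate 2 and 3.69 to 6.48 in the other 3 rapamycin libraries, against 1.19 ± 0.647 in vehicle. Erythroid markers were higher in 17 of 17 genes and T and NK cell markers lower in 12 of 12 (adjusted p = 0.00105 and 0.000369, with adjusted p = 0.591 and 0.514 under an estimated correlation). In edgeR, 1171 genes had an unadjusted p under 0.05, and DESeq2 called 115 genes, limma-voom 1 and limma on log2 TPM 0. Without rapamycin replicate 2, with only the 8 libraries compared or on log2 TPM, Bhlhe40 no longer passed and 0 genes were called, and 2 genes were called without palbociclib replicate 1 or without rapamycin replicate 4. Without vehicle replicate 1 the mean of genes raised in aged HSCs turned from -0.48 to 0.035, and without vehicle 4 that of T and NK cell markers went from -1.93 to -0.50, with both calls lost. Calls were also lost for oxidative phosphorylation genes without vehicle 3, glycolysis genes without vehicle 2 or rapamycin 1 or 2, and erythroid markers without vehicle 4 or rapamycin 2, while the ATF4, mitochondrially encoded and stromal lists stayed called without any single library. The 14 lists called (5 higher and 9 lower) became 8 with the 2 blood cell shares as covariates, 0 with an estimated correlation and 0 by fry. The immunoglobulin and B cell share did not overlap between these groups, so the fit with covariates cannot fully separate it from rapamycin.

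The third comparison asked how both drugs together changed the cells. Genes of the interferon response, the antiviral programme, were higher in 29 of 33 members, with a mean log2 fold change of 1.09. The list's mean log2 CPM was 5.31 ± 0.65 in combination and 4.17 ± 0.31 in vehicle libraries (SD, n = 4), with no overlap (exact permutation p = 0.029, adjusted p = 0.296). Rsad2, the antiviral enzyme viperin, averaged 72.4 ± 34.0 CPM against 18.3 ± 6.34, and Oasl2 163 ± 52.8 against 58.3 ± 10.1. Adjusted over the list alone, 16 members were called higher, against 0 over all genes (edgeR adjusted p = 1.28e-16, and adjusted p = 0.422 with an estimated correlation). S-phase genes were higher in 25 of 33, with 2 called over the list alone and 0 over all genes (adjusted p = 0.00213, and adjusted p = 0.422 with an estimated correlation).

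Markers of multipotent progenitors, the cells that HSCs give rise to, were higher in 9 of 12 genes, 0 of them called (adjusted p = 0.00675, and adjusted p = 0.422 with an estimated correlation). This list shares Mpo and Ctsg with the neutrophil list. Its mean log2 CPM was lowest in vehicle 1, palbociclib 2, combination 2 and rapamycin 1 (4.39, 4.45, 4.78 and 4.81). These libraries also had the lowest neutrophil shares (1.59%, 1.595%, 1.29% and 1.12%). Cd34 averaged 701 ± 128 CPM against 352 ± 122 in vehicle. B cell markers were lower in 11 of 11 genes, 9 called over the list alone and 0 over all genes (adjusted p = 3.78e-07, and adjusted p = 0.422 with an estimated correlation). Vehicle libraries varied most in these genes, with Cd79a, part of the B cell receptor, at 575 ± 1060 CPM (SD, n = 4) against 15.0 ± 9.59. Vehicle replicate 4 carried much of this fall: without it the list's mean log2 fold change went from -3.96 to -1.46 and that of Cd79a to -1.51.

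By edgeR 0 genes were called, 1611 had an unadjusted p under 0.05, and the lowest adjusted p was 0.218. DESeq2 called 206 genes, limma-voom 0 and limma on log2 TPM 0. The genes with the smallest p, none of which qualified, were Jpt2 (log2 fold change 0.81 ± 0.14 SE), Rsad2 (1.99 ± 0.39), F2r, the thrombin receptor (1.22 ± 0.25), Zfpm1, a partner of GATA1 (-2.52 ± 0.47), Rn7sk, the small nuclear RNA 7SK (-1.89 ± 0.36), and Qk, an RNA-binding protein gene (-1.26 ± 0.24). Of 13 lists called (6 higher and 7 lower), 0 were called with an estimated correlation and 0 by fry. Without vehicle replicate 2, 8 lists were called, S-phase genes not among them, as were 8 without blood lineage marker genes. The progenitor list was not called without vehicle 1 or combination 3, and the interferon list stayed called without any single library. The fatty acid synthesis list had a median log2 fold change of 0.26 and a mean of -0.06, and was not called (adjusted p = 0.0985).

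Adding rapamycin to palbociclib was the fourth comparison. All 29 G2/M genes and all 33 S-phase genes were lower in combination than in palbociclib libraries, by mean log2 fold changes of -0.63 and -0.28. None was called over all genes or over the list alone (edgeR adjusted p = 1.6e-19 and 5.79e-09, with adjusted p = 0.259 for both under an estimated correlation, and fry adjusted p = 0.529 for both). Mki67, the proliferation marker Ki-67, averaged 12.7 ± 6.55 CPM in combination and 27.2 ± 12.8 in palbociclib libraries (SD, n = 4). Neutrophil markers were lower in 14 of 19 genes in the same comparison (adjusted p = 0.00673, and adjusted p = 0.587 with an estimated correlation). Interferon response genes were higher in 30 of 33 and cytosolic ribosomal protein genes in 76 of 78, 0 of them called (adjusted p = 5.79e-10 and 1.42e-06, with adjusted p = 0.422 and 0.587 under an estimated correlation). No gene was called by edgeR, with 436 at an unadjusted p under 0.05, fewer than the 765 expected by chance. With a replicate block within each palbociclib level, added after the results were seen, edgeR called 7 genes, Crem and immunoglobulin genes. In that fit 722 genes had an unadjusted p under 0.05. DESeq2 called 18, limma-voom 1 and limma on log2 TPM 0. The smallest p belonged to Crem, a regulator of cyclic AMP response, at 317 ± 63.8 CPM against 114 ± 24.8 (log2 fold change 1.47 ± 0.26, edgeR adjusted p = 0.485). Of 18 lists called, 8 were higher and 10 lower. Without palbociclib replicate 1 the erythroid list turned to a mean of 0.34, and the neutrophil list was not called without palbociclib 1 or 3 or combination 1 or 2, while the G2/M, S-phase, interferon and ribosomal protein lists stayed called without any single library. Combination replicate 2 carried part of the G2/M fall, with a mean of -0.41 without it.

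Adding palbociclib to rapamycin, the fifth comparison, gave 5 called genes by edgeR, 4 higher and 1 lower. Irf7, a master regulator of the interferon response (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481), was 5.58-fold higher, at 186 ± 87.9 CPM in combination and 33.4 ± 3.82 in rapamycin libraries (SD, n = 4). Gpr4, a proton-sensing receptor gene (ENSMUSG00000044317, chromosome 7, 19212538 to 19224174), was 4.52-fold higher, at 95.5 ± 10.9 against 21.1 ± 5.36. Selp, a gene known to be raised in aged HSCs (ENSMUSG00000026580, chromosome 1, 164115264 to 164150026), was 3.48-fold higher, at 216 ± 24.3 against 62.0 ± 17.5. Bhlhe40 was 3.16-fold higher, at 52.2 ± 3.69 against 16.5 ± 4.78. Qk, whose product binds RNA (ENSMUSG00000062078, chromosome 17, 10202601 to 10319854), was 3.33-fold lower, at 27.1 ± 6.61 against 90.2 ± 12.4.

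The edgeR adjusted p values were 0.0361 for Irf7, 0.0265 for Gpr4, 0.0197 for Selp, 0.0245 for Bhlhe40 and 0.0197 for Qk, and the log2 fold changes 2.48 ± 0.40, 2.18 ± 0.34, 1.80 ± 0.25, 1.66 ± 0.25 and -1.74 ± 0.25 (SE). Mean levels of Selp, Gpr4 and Bhlhe40 in vehicle (153, 55.1 and 66.8 CPM) lay between those of the 2 groups or, for Bhlhe40, above both. Next in p came Zfpm1 (-2.64 ± 0.48, adjusted p = 0.0656) and Znrf2 (-1.51 ± 0.28, adjusted p = 0.0844), which did not qualify.

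**Figure D2:**
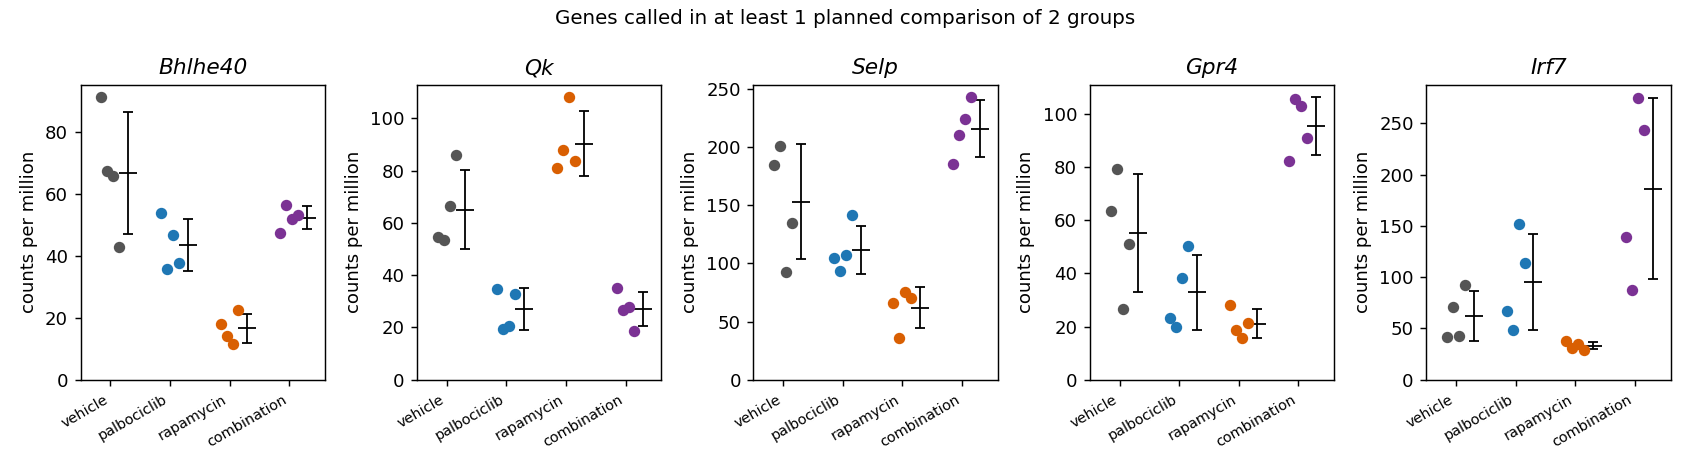
CPM of the genes called in at least 1 planned comparison of 2 groups, with one point per library, 4 libraries per group, and black bars for the mean ± SD. Rapamycin libraries have the lowest mean of Bhlhe40, Selp, Gpr4 and Irf7, and Qk is lower in both groups given palbociclib.

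Interferon response genes were higher in 29 of 33 members, 1 called over all genes and 19 adjusted over the list alone, with a mean log2 fold change of 1.41 (edgeR adjusted p = 1.78e-21, and adjusted p = 0.155 with an estimated correlation). The list mean was 5.31 ± 0.65 in combination and 4.10 ± 0.17 in rapamycin libraries (n = 4, no overlap, exact permutation p = 0.029, adjusted p = 0.148). Glycolysis genes were higher in 17 of 19, with 8 called over the list alone and 0 over all genes (adjusted p = 1.01e-06, and adjusted p = 0.155 with an estimated correlation), and their list mean was 8.21 ± 0.06 against 7.83 ± 0.10. Ldha, which makes lactate, averaged 3070 ± 166 CPM against 1810 ± 201. Proteasome genes were higher in 30 of 31, with 4 called over the list alone and 0 over all genes (adjusted p = 4.04e-05, and adjusted p = 0.322 with an estimated correlation). Genes of the ATF4 response were higher in 15 of 19, 2 of them called over the list alone, and those of the unfolded protein response of the endoplasmic reticulum in 18 of 19, also with 2 (adjusted p = 0.00567 and 0.000168, with adjusted p = 0.294 and 0.406 under an estimated correlation). Lysosome and autophagy genes were higher in 17 of 23, with 1 called over the list alone and 0 over all genes (adjusted p = 0.0106, and adjusted p = 0.385 with an estimated correlation). Erythroid markers were lower in 16 of 17 and stromal markers in 11 of 11, 0 of them called (adjusted p = 3.83e-08 and 0.000206, with adjusted p = 0.322 and 0.294 under an estimated correlation).

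In this comparison 1498 genes had an unadjusted p under 0.05, and DESeq2 called 202, limma-voom 77 and limma on log2 TPM 13, each including the 5 genes. Of the 31 lists, 19 were called (11 higher and 8 lower), 0 with an estimated correlation and 4 by fry. The 5 calls became 0 without any 1 of rapamycin replicates 1, 2, 3 and 4 or of combination replicates 3 and 4, 1 without combination replicate 2, and 2 without combination replicate 1. They became 16 without vehicle replicate 3 and 10 without palbociclib replicate 2, and 56 with only the 8 libraries compared. Irf7 was not called with 1 surrogate variable, without vehicle replicate 2 or without the 3 libraries of lowest correlation, Gpr4 not with the blood cell shares as covariates, and Bhlhe40 not with library totals alone. The lysosome list was not called without rapamycin replicate 1.

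**Figure D3:**
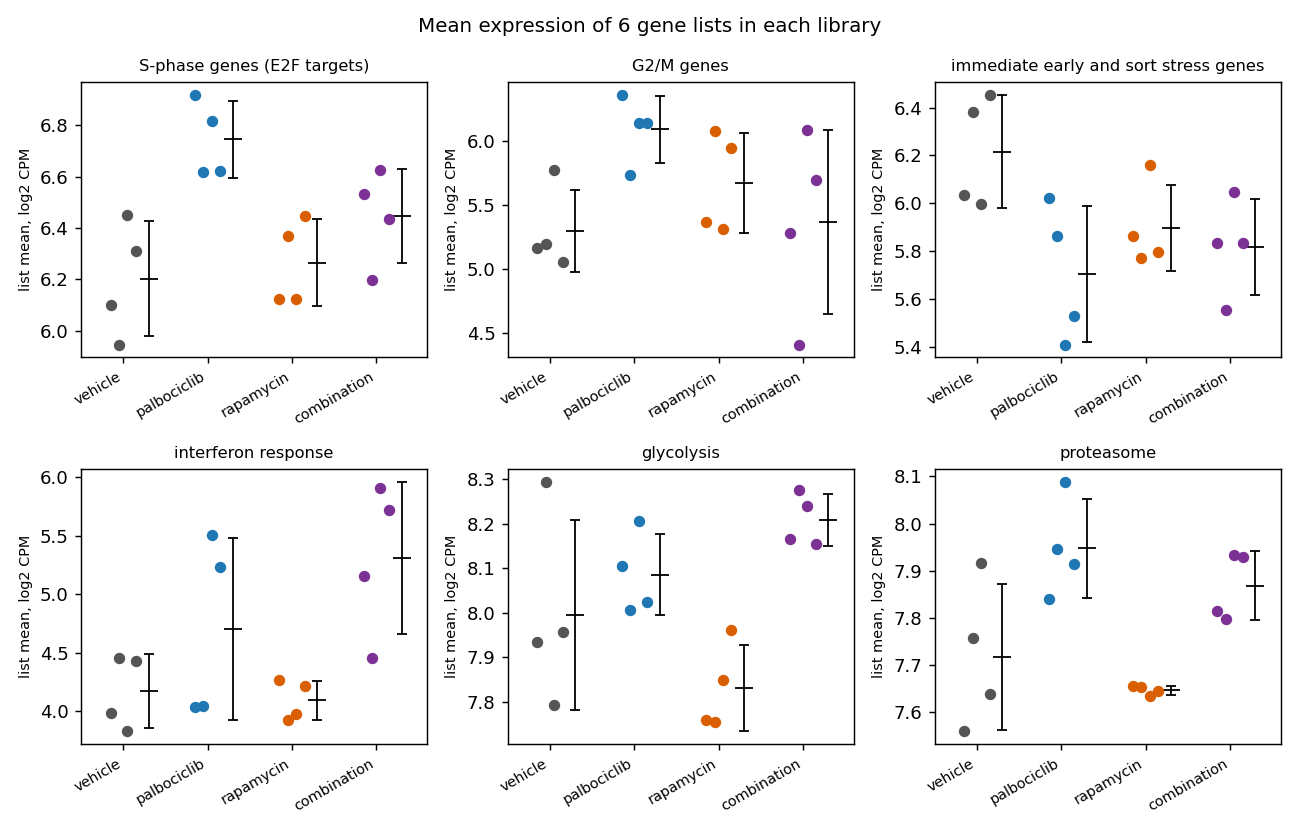
Mean log2 CPM of 6 gene lists in each library, with one point per library, 4 libraries per group, and black bars for the mean ± SD. S-phase means run higher in palbociclib (6.74 ± 0.15) than in vehicle (6.20 ± 0.22), and interferon means higher in the combination (5.31 ± 0.65) than in rapamycin libraries (4.10 ± 0.17).

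The sixth comparison set the single drugs against each other. Qk was 3.35-fold higher after rapamycin than after palbociclib, at 90.2 ± 12.4 against 26.9 ± 8.05 CPM (SD, n = 4, log2 fold change 1.75 ± 0.25 SE, edgeR adjusted p = 0.0376), and it was the 1 gene called. S-phase genes were lower after rapamycin in 32 of 33 members, with 9 called over the list alone and 0 over all genes (adjusted p = 6.17e-14, and adjusted p = 0.0954 with an estimated correlation). Proteasome genes were lower in 31 of 31, with 4 called over the list alone and 0 over all genes (adjusted p = 5.53e-10, and adjusted p = 0.214 with an estimated correlation). Psmd13, a subunit of the proteasome's cap, averaged 118 ± 13.8 against 189 ± 22.9 CPM. Sterol synthesis genes were lower in 17 of 22, with 2, Fdps and Ebp, called over the list alone (adjusted p = 0.00201, and adjusted p = 0.214 with an estimated correlation). HSC identity genes were higher in 24 of 30, with 1, Hlf, called over the list alone (adjusted p = 5.84e-06, and adjusted p = 0.362 with an estimated correlation), and Hlf averaged 121 ± 17.6 after rapamycin and 54.1 ± 17.3 after palbociclib. Erythroid and stromal markers were also higher after rapamycin, in 15 of 17 and 11 of 11 genes (adjusted p = 3.15e-05 and 0.00549, with adjusted p = 0.362 for both under an estimated correlation).

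In edgeR 1237 genes had an unadjusted p under 0.05, and DESeq2 called 96 genes, limma-voom 4 and limma on log2 TPM 0. Of 17 lists called (6 higher and 11 lower), 0 were called with an estimated correlation and 2 by fry. Qk stayed called when vehicle 4, combination 1 or combination 4 was left out, and 2 genes were called without palbociclib 4. Leaving out any 1 of vehicle 1, 2 and 3, palbociclib 1, 2 and 3, rapamycin 1, 2, 3 and 4 and combination 2 and 3 left 0 calls. Qk was also not called with 1 surrogate variable, with the replicate number as a block or with only the 8 libraries compared. On log2 TPM and without the 3 libraries of lowest correlation it was not called either.

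Whether the effect of one drug depended on the other was tested as an interaction. The smallest p of the interaction belonged to Bhlhe40 (log2 2.28 ± 0.34 SE), Selp (2.25 ± 0.35) and Gpr4 (2.92 ± 0.46), each at an edgeR adjusted p of 0.051. Their means were lowest with rapamycin alone (16.5, 62.0 and 21.1 CPM), lower with palbociclib alone (43.5, 112 and 32.9) than in vehicle (66.8, 153 and 55.1), and 52.2, 216 and 95.5 with both drugs. In the other direction Nucks1, Usp9x and Fancd2 had the smallest p and did not qualify (-1.32 ± 0.27, -1.28 ± 0.30 and -2.66 ± 0.65, adjusted p = 0.284, 0.464 and 0.471). The 0 genes called by edgeR stood beside 868 at an unadjusted p under 0.05, 45 called by DESeq2, 8 by limma-voom and 0 on log2 TPM. Bhlhe40, Selp and Gpr4 alone were called by edgeR with RLE size factors, with the stricter filter and without mitochondrial, ribosomal protein, haemoglobin and predicted genes, and 0 genes with library totals or blood cell covariates. Without vehicle replicate 3, 5 genes were called, these 3 among them, 1 (Bhlhe40) without vehicle replicate 4 or rapamycin replicate 4, and 0 without any other single library. With the preset correlation 15 lists were called (8 higher and 7 lower), with an estimated one 0 (lowest adjusted p = 0.166), and by fry 0. A joint test of any difference among the 4 groups called 2 genes, Bhlhe40 and Qk, with 1522 at an unadjusted p under 0.05. It called 0 genes without any 1 of palbociclib 3, rapamycin 1, 2 and 3 and combination 2, 3 and 4, 1 without palbociclib 1 or 4 or combination 1, 4 without vehicle 1 and 14 without vehicle 3.

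Transcripts of the drug targets did not pass the test against vehicle in any group. Cdk4 averaged 544 ± 21.6 CPM in vehicle, 625 ± 43.4 in palbociclib, 476 ± 40.0 in rapamycin and 599 ± 73.5 in combination libraries (SD, n = 4). Cdk6 averaged 130 ± 50.5, 205 ± 85.0, 133 ± 49.3 and 253 ± 44.8 in the same order. The D cyclins, which activate both kinases, averaged 27.4, 32.1, 17.7 and 30.7 CPM for Ccnd1, 302, 302, 355 and 358 for Ccnd2, and 575, 720, 500 and 721 for Ccnd3. Rb1, the target of the kinases, averaged 12.3 ± 5.48, 22.0 ± 8.61, 25.6 ± 11 and 16.4 ± 3.41 CPM. Mtor averaged 19.9 ± 7.28, 27.8 ± 7.10, 22.2 ± 7.41 and 23.6 ± 7.13 CPM, and Fkbp1a, which encodes the protein that rapamycin binds, 419 ± 32.2, 288 ± 59.3, 350 ± 87.6 and 380 ± 57.2. The lowest edgeR adjusted p among these 8 genes was 0.314, for Cdk6 in the combination.

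Genes that define the sort were detected in every group. Kit averaged 235 ± 118, 272 ± 109, 455 ± 95 and 305 ± 95.5 CPM in vehicle, palbociclib, rapamycin and combination libraries (SD, n = 4). Ly6a, which encodes Sca-1, averaged 455 ± 411, 296 ± 157, 173 ± 29.9 and 654 (single combination libraries 500 to 793). Without vehicle replicate 4, at 1006 CPM, its log2 fold change against vehicle went from -1.40 to -0.65 with rapamycin and from 0.52 to 1.27 with both drugs, and without vehicle replicate 3 to -1.74 and 0.18. Slamf1, which encodes CD150, averaged 38.3 ± 14.7, 25.6 ± 11.4, 22.0 ± 7.77 and 32.8 ± 7.90, and Cd48, which the sort selects against, 21.7 ± 18.3, 29.1 ± 20.8, 18.1 ± 8.62 and 27.9 ± 24.1. No test against vehicle passed for any of the 4.

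The changes of the single drugs were then compared across genes, which are not independent replicates. Fold changes of palbociclib and of rapamycin against vehicle correlated with r = 0.556 over 15308 genes, and 67.5% of genes shared a sign (66.7% on average in the simulations described next, with a highest of 67.4%). Both comparisons used the same vehicle libraries, and 3 simulated unchanged groups, 1 of them shared in the same way, gave r = 0.498 on average (0.469 to 0.526 in 50 simulations). The covariance was 0.495, against a simulated mean of 0.324 and a simulated highest of 0.356, a difference of 0.171 from the mean. With 2 separate vehicle libraries for each drug, r averaged -0.035 (-0.143 to 0.084 over 6 splits), the covariance -0.0337 and the share of genes with the same sign 48.8%, against 0.511, 0.262 and 66.7% on the same scale with shared libraries. The covariance beyond shared controls was therefore not found with split vehicle libraries.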

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

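The rules for values that stand apart were set before the data were examined, and the interaction lists and single values below were picked out by those rules after the results were seen.

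Among 100 groups of 4 values checked, 10 single values stood apart from the other 3, where 5 were expected by chance. Ribosomal protein genes made up 2.59% of the counts of vehicle replicate 3 and 4.82% to 5.15% of the other vehicle libraries. Haemoglobin genes made up 0.132% of rapamycin replicate 2 and 0.0358% to 0.0476% of the other rapamycin libraries. Cdk6 was at 331 CPM in palbociclib replicate 4 (145 to 172 in the others) and at 320 in combination replicate 1 (223 to 240). Ccnd2 was at 409 CPM in vehicle replicate 1 (262 to 274), and Ccnd3 at 395 in palbociclib replicate 2 (806 to 855). Mtor was at 11.1 CPM in rapamycin replicate 3 (25.6 to 26.3), and Fkbp1a at 371 in vehicle replicate 4 (432 to 438). Slamf1 was at 60.4 CPM in vehicle replicate 1 (29.5 to 32.8) and at 21.1 in combination replicate 3 (35.1 to 38.0).

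The effect of palbociclib on 15 lists differed between libraries with and without rapamycin when tested as an interaction with the preset correlation, and on 0 lists with an estimated one. Mean log2 interaction fold changes above 0 were found for glycolysis (0.32), the ATF4 response (0.38), lysosome and autophagy (0.43), cytosolic ribosomal proteins (0.19), the interferon response (0.85), immediate early genes (0.36), the unfolded protein response (0.31) and genes raised in aged HSCs (0.35). Those below 0 were S-phase genes (-0.30), G2/M genes (-0.997), mitochondrially encoded genes (-1.64, with a median of -1.10, since mt-Nd4l, at 0 CPM in all 4 vehicle libraries, had -9.84 ± 2.90 SE) and the markers of megakaryocytes (-2.18), erythroid cells (-1.88), neutrophils (-0.59) and stromal cells (-2.48). Of these 15 lists, the last 4 mark cells that the sort excludes. With blood cell covariates, an alternative added after the results were seen, the mean of the unfolded protein response turned to -0.019 and that of neutrophil markers to 0.04, and the ATF4, ribosomal protein, interferon, megakaryocyte and erythroid lists were no longer called. The neutrophil markers were adjusted there for their own share, so their value decides nothing. Leaving out 1 library moved some means by over 1.5-fold. Genes raised in aged HSCs turned to -0.12 without vehicle 1, and ribosomal proteins went to 0.052 without vehicle 4, the unfolded protein response to 0.096 without combination 3, megakaryocyte markers to -1.03 without rapamycin 3, erythroid markers to -0.51 without palbociclib 1 and neutrophil markers to -0.27 without combination 2, each with the call lost. Glycolysis went to 0.21 without vehicle 2 and stayed called.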

How the results depend on the processing

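The alternatives with blood cell covariates, without the 3 libraries of lowest correlation, with robust shrinkage, without blood lineage marker genes and with a replicate block within each palbociclib level were added after the results were seen, and the averaged contrasts were added then too. Where a result moved, the cause was not tested. The blood cell covariates are the shares of the neutrophil list and of the immunoglobulin and B cell genes. Neutrophil and B cell markers are thus adjusted for their own genes in those fits. The immunoglobulin and B cell share did not overlap between rapamycin and vehicle libraries, so there it cannot be fully told apart from rapamycin.

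Gene counts by edgeR moved as follows. For palbociclib against vehicle (0 genes) DESeq2 called 137 and the fit without 3 libraries 1. For rapamycin against vehicle (1 gene) DESeq2 called 115, limma on log2 TPM 0 and the fit of only the 8 libraries compared 0. For the combination against vehicle (0 genes) DESeq2 called 206, the fit without 3 libraries 1 and that with blood cell covariates 1 (Chil3). For the combination against palbociclib (0 genes) DESeq2 called 18 and limma-voom 1.

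For the combination against rapamycin (5 genes) there were 16 calls without a filter, 10 with the stricter filter, 56 with only the 8 libraries compared, 202 by DESeq2, 77 by limma-voom, 13 on log2 TPM, 10 without blood lineage marker genes and 17 at an adjusted p of 0.1. Irf7 was lost with a surrogate variable (4 calls), without vehicle replicate 2 (5) and without 3 libraries (5), Gpr4 with blood cell covariates (7) and Bhlhe40 with library totals (5). For rapamycin against palbociclib (1 gene) there were 0 with a surrogate variable, 0 with only the 8 libraries compared, 96 by DESeq2, 4 by limma-voom, 0 on log2 TPM, 0 without 3 libraries and 3 with blood cell covariates.

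For the interaction (0 genes) RLE size factors gave 3, no filter 4, the stricter filter 3, a surrogate variable 2, leaving out mitochondrial, ribosomal protein, haemoglobin and predicted genes 3, DESeq2 45, limma-voom 8, the fit without 3 libraries 3, robust shrinkage 3, leaving out blood lineage marker genes 3 and an adjusted p of 0.1 gave 4. Each count of 3 was Bhlhe40, Gpr4 and Selp, and blood cell covariates and library totals gave 0. For any difference among the groups (2 genes) no filter gave 96, a surrogate variable 4, leaving out mitochondrial, ribosomal protein, haemoglobin and predicted genes 10, DESeq2 385, limma-voom 13, log2 TPM 1, blood cell covariates 10, robust shrinkage 4 and an adjusted p of 0.1 gave 12.

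For palbociclib averaged over rapamycin (42 genes) library totals gave 26, a surrogate variable 65, blood cell covariates 56, DESeq2 555, limma-voom 334, log2 TPM 18, the fit without 3 libraries 14 and an adjusted p of 0.1 gave 185. Of the 42 genes 26, 41, 36, 42, 42, 15 and 8 were among these in the same order up to the fit without 3 libraries, and 31 among the 53 without a filter. For rapamycin averaged over palbociclib (0 genes) no filter gave 23 and DESeq2 61.

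Replicate numbers as a block gave 1 gene for palbociclib against vehicle, 11 for the combination against rapamycin, 2 for rapamycin against palbociclib (Brd1 and Igkv5-39, named after their values were seen, and not Qk), 1 for any difference and 3 for rapamycin averaged over palbociclib. With this block the log2 fold change of Ccnd2 after palbociclib was -0.008 and the correlation of the single drugs 0.493. The labels do not pair libraries by number, and after removing group means 24 same-numbered pairs correlated at -0.210 to 0.348 (median 0.0422, against -0.0195 for other pairs), with 7 pairs above 0.1 and 7 libraries closest to one of their own number, so the block was not used. The pairs of rapamycin and vehicle libraries (0.248, 0.014, 0.186 and 0.111 for numbers 1 to 4) and those of combination and palbociclib libraries (0.010, 0.348, 0.285 and 0.037) were all positive, but not all above 0.1. Vehicle 3 and rapamycin 3 also lay together on the first principal component (-112 and -110), but apart on component 2 (-78.3 and 8.9). Neutrophil shares were close in vehicle and rapamycin libraries 1, 2 and 3 (1.59% and 1.12%, 7.54% and 7.18%, 5.04% and 5.28%). So were those of palbociclib and combination libraries 2, 3 and 4 (1.595% and 1.29%, 9.11% and 7.94%, 6.82% and 5.73%). They differed in vehicle 4 and rapamycin 4 (2.43% and 6.83%) and in palbociclib 1 and combination 1 (10.9% and 2.98%). These are hints from the data and not from the design, so pairing by number stays open. A block within each palbociclib level gave 13 genes for rapamycin against vehicle (Bhlhe40 among them), 7 for the combination against palbociclib, 5 for the interaction and 12 for averaged rapamycin, with 1426, 722, 1218 and 996 at an unadjusted p under 0.05, and 16, 18, 15 and 18 lists. Most of these genes were immunoglobulin genes, and the other comparisons cannot be estimated with this block. If libraries with and without palbociclib were prepared apart, that could therefore not be told apart from palbociclib.

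With an estimated correlation, camera called 0 lists in each of the 6 comparisons of 2 groups, the interaction and both averages, where the preset one called 14, 14, 13, 18, 19, 17, 15, 16 and 16. By fry 2 lists were called for palbociclib against vehicle, 0 for rapamycin against vehicle, 0 for the combination against vehicle, 0 for it against palbociclib, 4 for it against rapamycin, 2 for rapamycin against palbociclib, 0 for the interaction, 5 for averaged palbociclib and 0 for averaged rapamycin. Blood cell covariates left 8 lists for rapamycin against vehicle, and leaving out blood lineage marker genes 8 for the combination against vehicle.

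Some small fold changes turned sign. Ccnd2 after palbociclib (0.004) was at -0.011 with RLE size factors, -0.014 with library totals, -8.1e-05 without a filter, -0.017 with the stricter filter, -0.066 with a surrogate variable, -0.024 without mitochondrial, ribosomal protein, haemoglobin and predicted genes, -0.016 with only the 8 libraries compared, -0.010 by DESeq2, -0.035 by limma-voom and -0.143 without 3 libraries. Ccnd1 was at -0.036 after palbociclib and -0.156 in the combination with blood cell covariates, and at -0.232 and -0.294 without 3 libraries. Cdk6 after rapamycin was at -0.037 with a surrogate variable, -0.014 by limma-voom and -0.056 on log2 TPM. Mtor was at -0.012 after palbociclib on log2 TPM, at -0.253 on log2 TPM and -0.038 by limma-voom in the combination, and at -0.210 after rapamycin with blood cell covariates. Kit after palbociclib was at -0.043 by limma-voom and -0.216 without 3 libraries, and in the combination at -0.050 without 3 libraries. Cd48 after rapamycin was at 0.123 on log2 TPM and 1.057 with blood cell covariates.

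Without 3 libraries the means of B cell and T cell markers after palbociclib turned to 1.21 and 1.16, and that of megakaryocyte markers after rapamycin to -0.14. With blood cell covariates B cell markers turned to 1.74 after rapamycin and 0.017 for averaged rapamycin, HSC identity genes to -0.18 and macrophage markers to 0.32 for averaged rapamycin, and the unfolded protein response to 0.24 after rapamycin and -0.019 for the interaction. Neutrophil markers turned to -0.12 after palbociclib, 0.29 for the combination against palbociclib and 0.04 for the interaction. Since the covariates were made from the same genes, the turns of B cell and neutrophil markers decide nothing.

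The correlation between the single drugs (0.556) was 0.457 by limma-voom, 0.482 on log2 TPM, 0.696 with blood cell covariates, 0.689 without 3 libraries and -0.035 with 2 separate vehicle libraries for each drug.

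Leaving out each library in turn gave 0 to 0 genes for palbociclib against vehicle, 0 to 2 for rapamycin against vehicle, 0 to 0 for the combination against vehicle, 0 to 0 for it against palbociclib, 0 to 16 for it against rapamycin, 0 to 2 for rapamycin against palbociclib, 0 to 5 for the interaction, 0 to 14 for any difference, 6 to 58 for averaged palbociclib and 0 to 0 for averaged rapamycin. Lists called ran from 9 to 14, 10 to 15, 8 to 19, 12 to 19, 15 to 20, 15 to 19, 12 to 15, 14 to 19 and 11 to 17 in the same order without the joint test, and the correlation between the single drugs from 0.476 to 0.663.

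Some fold changes against vehicle also turned sign when a single library was left out. After palbociclib Ccnd2 ran from -0.255 without palbociclib 2 to 0.191 without vehicle 1, Kit from -0.108 without palbociclib 2 to 0.595 without vehicle 1, Ly6a from -0.957 without vehicle 3 to 0.128 without vehicle 4, and Cd48 from -0.139 without palbociclib 3 to 1.091 without vehicle 4. After rapamycin Cdk6 ran from -0.180 without rapamycin 2 to 0.241 without rapamycin 3, Mtor from -0.074 without vehicle 3 to 0.378 without rapamycin 3, and Cd48 from -0.563 without vehicle 1 to 0.405 without vehicle 4. In the combination Ccnd1 ran from -0.055 without vehicle 4 to 0.449 without vehicle 2, Slamf1 from -0.328 without vehicle 2 to 0.083 without vehicle 1, and Cd48 from -0.437 without combination 3 to 1.029 without vehicle 4.

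After palbociclib, B cell markers ran from -3.71 without palbociclib 1 to 0.52 without vehicle 4, and T and NK cell markers from -3.34 to 0.17 without the same libraries. Among other lists, megakaryocyte and platelet markers ran from -0.122 without rapamycin 3 to 1.273 without rapamycin 2 for rapamycin against vehicle, and from -1.447 without palbociclib 3 to -0.156 without palbociclib 1 for the combination against palbociclib. Erythroid markers ran from -1.413 without combination 1 to 0.339 without palbociclib 1 in that comparison, and cytosolic ribosomal proteins from -0.008 without vehicle 3 to 0.148 without vehicle 4 for averaged rapamycin.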

Other observations

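All tests in this part were chosen after the results were seen, and the 2 averaged contrasts were added then too.

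Palbociclib averaged over libraries with and without rapamycin called 42 genes by edgeR, 14 higher and 28 lower, among 2115 at an unadjusted p under 0.05. The labels do not say whether libraries with and without palbociclib were prepared together. A difference in preparation between them could thus not be told apart from the drug. Nfix, a transcription factor gene of stem cells, fell 3.51-fold (log2 fold change -1.81 ± 0.26 SE, adjusted p = 0.00958), at 13.3 ± 5.18 CPM with palbociclib and 15.3 ± 2.92 with both drugs against 51.4 ± 15.7 in vehicle and 48.7 ± 24.4 with rapamycin (SD, n = 4). Qk fell 2.84-fold (-1.50 ± 0.17, adjusted p = 0.00264), Znrf2 2.88-fold (-1.52 ± 0.20, adjusted p = 0.00758), Brd1, a chromatin reader, 2.81-fold (-1.49 ± 0.22, adjusted p = 0.00958), Zfpm1 5.04-fold (-2.33 ± 0.33, adjusted p = 0.00958) and Khdrbs3 7.28-fold (-2.86 ± 0.46, adjusted p = 0.0174). Eif4a1, a helicase of translation initiation, rose 1.62-fold (0.70 ± 0.13, adjusted p = 0.0390), and Jpt2 (0.68 ± 0.10, adjusted p = 0.00958), Irf7 (1.55, adjusted p = 0.0288), Pcna (0.53, adjusted p = 0.0390) and the proteasome genes Psmd2 (0.51 ± 0.09, adjusted p = 0.0268) and Psmd13 (0.45, adjusted p = 0.0430) rose too. Cul3 (-1.76, adjusted p = 0.0174) and Egln1 (-1.48, adjusted p = 0.0298) fell, and Lgals9 (0.54, adjusted p = 0.0354) and Cdipt (0.47, adjusted p = 0.0477) rose.

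In this average S-phase genes were higher in 31 of 33 members, 1 called over all genes and 10 adjusted over the list alone (edgeR adjusted p = 5.67e-11, and adjusted p = 0.219 with an estimated correlation). Interferon response genes were higher in 30 of 33, with 3 and 20 called (adjusted p = 2.43e-17, and adjusted p = 0.231 with an estimated correlation). Proteasome genes were higher in 28 of 31, with 2 called either way (adjusted p = 5.69e-07, and adjusted p = 0.231 with an estimated correlation). In all, 16 of the 31 lists were called, 9 higher and 7 lower, with 0 under an estimated correlation and 5 by fry. The 42 calls were 16 without vehicle replicate 1, 7 and 10 without palbociclib 3 and 4, 13, 17, 19 and 20 without rapamycin 1 to 4, 19, 23, 7 and 6 without combination 1 to 4, and 58 without vehicle 4. Nfix, Qk, Znrf2, Brd1, Zfpm1 and Jpt2 stayed called without any single library and without the 3 libraries of lowest correlation, where 8 of the 42 were kept. In the 16 fits that left out 1 library, calls were lost in 2 for Cul3, 3 for Khdrbs3, 9 for Irf7 and Psmd2, 10 for Egln1 and Lgals9, 12 for Eif4a1 and Pcna, 13 for Psmd13 and 14 for Cdipt. Rapamycin averaged over palbociclib called 0 genes by edgeR, with 711 at an unadjusted p under 0.05, fewer than the 765 expected by chance, while DESeq2 called 61, limma-voom 0 and limma on log2 TPM 0. With a replicate block within each palbociclib level edgeR called 12 genes, with 996 at an unadjusted p under 0.05. Oxidative phosphorylation genes were lower in 44 of 46 (adjusted p = 4.26e-06, and adjusted p = 0.344 with an estimated correlation).

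Regrouping the libraries into other splits asked whether chance can be excluded for the counts of calls. Where the real count was 0, every split reaches it, so those counts decide nothing. This holds for the genes of palbociclib against vehicle (35 of 35 splits, highest other 6), of the combination against vehicle (35, highest other 0) and against palbociclib (35, highest other 0), of the interaction (100 of 100, highest other 1) and of averaged rapamycin (100, highest other 2). For palbociclib against vehicle 4 of 35 splits, the real one included, gave 14 or more lists (highest other 16). For rapamycin against vehicle 3 of 35 gave 1 gene or more (highest other 2) and 2 gave 14 lists or more (highest other 14), and for the combination against vehicle 7 gave 13 lists or more (highest other 15). Chance was not excluded for any of these, and the median of the other splits was 10.5, 9 and 10.5 lists. For the combination against palbociclib only the real split, 1 of 35, reached 18 lists (highest other 16). For the combination against rapamycin 1 of 35 reached 5 genes (highest other 0) and 1 reached 19 lists (highest other 15). For rapamycin against palbociclib 1 of 35 reached 1 gene (highest other 0) and 3 reached 17 lists (highest other 19). The median of the other splits was 11, 9.5 and 9.5 lists for these 3 comparisons, and 1 of 35 is the smallest share that 4 against 4 libraries allow.

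Over 100 splits of all libraries the interaction's 15 lists were reached in 6 (highest other 18), the 2 genes of the joint test in 5 (highest other 6), and averaged rapamycin's 16 lists in 8 (highest other 20). The 42 genes of averaged palbociclib were reached in 2, the other with 231, and its 16 lists in 10 (highest other 20). The split with 231 calls put 6 of the 8 libraries given palbociclib on one side with 2 others, at a median neutrophil share of 7.36% against 2.01% on the other side (6.27% and 5.16% for the real split). It may reflect a structure of the samples beside treatment, although treatment is part of this split too. With the log2 neutrophil share as a covariate this split called 0 genes, while the real one called 58, 41 of them among the 42, and with both blood cell shares 0 and 56, 36 of them among the 42. With the neutrophil share the 231 genes kept a median of 0.649 of their log2 fold change (median 1.26 before and 0.67 after), and their SE rose by a median of 1.45-fold (median 0.26 before and 0.33 after), so the calls ended through both. Whether the neutrophil share is such a structure therefore stays open. The 42 genes kept a median of 0.989 of theirs, so this share does not account for them, and other structures were not tested. Taken singly, chance was excluded for the lists of the combination against palbociclib, the genes and lists of the combination against rapamycin, the gene of rapamycin against palbociclib and the genes of averaged palbociclib. Adjusted over all 19 counts, the lowest share of splits was 0.109, so chance was excluded for none. The 19 include the counts of 0, which decide nothing, and the few splits set a floor on each share. The adjusted value could thus hardly fall under 0.05, and it does not show that chance made the counts.

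Higher S-phase genes after palbociclib, a difference of 0.54 ± 0.13 (SE) in list mean, could come from RNA of other blood cells, from libraries that stand apart or from scaling. With the 2 blood cell shares as covariates it was 0.56 ± 0.13, and in 13 libraries 0.72 ± 0.14. The smallest mean log2 fold change under 3 other scalings was 0.46. That is another measure than the list mean, and it lay below the mean log2 fold change with TMM given above. The fit of 13 libraries left vehicle 1 and 2, with list means of 6.10 and 5.95. It dropped vehicle 3 and 4, at 6.45 and 6.31, so the difference had to rise. That rise is thus no separate test of the 3 libraries, and shows only that vehicle 3 and 4 narrowed the difference. Rapamycin 3 is in neither group. The other values argue against neutrophil and B cell RNA and scaling as the whole cause. The 2 shares do not measure RNA of other cell types, which stays open. Over 16 libraries the S-phase mean and the log2 neutrophil share had Pearson r = 0.471 (permutation p = 0.0663, adjusted p = 0.0884) and Spearman rho = 0.541 (permutation p = 0.0332), so a part from blood cells stays open. A CDK4/6 inhibitor would be expected to lower E2F targets, and the time between the last dose and the sort, which could allow a rebound, is not given in the sources used here. The cells were sorted in G0 or G1, so the S-phase and G2/M lists do not measure the share of HSCs that cycle. G2/M transcripts were still present, with Ccnb1 at 185 to 351 CPM in palbociclib and 103 to 190 in vehicle libraries. Their source was not tested.

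Higher interferon response genes in the combination than with rapamycin, a difference of 1.21 ± 0.38 (SE) in list mean, may have the same origins. With blood cell covariates the difference was 0.96 ± 0.37, which leaves RNA of other blood cells open as a part of it (Pearson r = 0.301 with the neutrophil share, permutation p = 0.255). In 13 libraries it was 1.17 ± 0.46. The smallest mean log2 fold change under 3 other scalings was 1.28, below the mean log2 fold change with TMM given for this comparison. These values argue against the other explanations as the whole cause. Interferon means of single libraries were 4.04, 4.04, 5.50 and 5.23 with palbociclib and 5.15, 4.46, 5.91 and 5.72 with both drugs, so libraries of one treatment differed by more than 1 log2 unit.

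The share of neutrophil RNA may reflect a single source, such as neutrophil lineage RNA carried along at varying amounts, or the drugs. Over 7 granule genes the median SD of the log2 ratio to S100a8 was 0.53, while the SD of S100a8 itself was 1.27. S100a9 and Lcn2 kept their ratios best, at 0.14 and 0.27. Ngp and Ltf varied more, at 0.51 and 0.53, and Retnlg, Camp and Mmp8 most, at 0.65, 0.85 and 0.85. Chil3, not among the 7, was at 3257, 583, 12749 and 8494 CPM in combination libraries, and Camp at 581, 376, 1776 and 1708. In vehicle libraries Chil3 was at 645, 3186, 2382 and 2112, and Camp at 791.5, 3384, 3386 and 1084. A single source therefore stays open. With the 2 blood cell shares as covariates, edgeR called 1 gene for the combination against vehicle, Chil3, and 0 without them. Chil3 is itself part of the neutrophil share, and no other test of a change of composition with treatment was made. Treatment groups held 7.10% of the variance of the log2 share (upper end of the 95% interval from the noncentral F distribution 23.4%, and 2.25% to 23.8% leaving out each library), which argues against the drugs as the source of most of it, while a smaller effect of the drugs stays open. HSC identity genes were lower where the share was higher, with Pearson r = -0.551 over 16 libraries (permutation p = 0.0283, adjusted p = 0.0566 over 4 relations), Spearman rho = -0.488 (permutation p = 0.0579), and r = -0.435 without the 2 farthest libraries. Whether libraries differ in the purity of the sorted cells therefore stays open.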
